A study of Mus musculus with 9 samples.

How the data were processed

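Gene expression was profiled by microarray in 9 samples of sorted leukaemic marrow cells from mice, 4 WT and 5 Ezh2-null, grouped and numbered by the sample titles. The labels call them biological replicates and do not say which primary leukaemia each secondary recipient received, so leukaemias of one origin among them cannot be ruled out. Per the labels' protocols, total RNA was amplified by a whole-transcriptome method and labelled with biotin before hybridisation. The submitters' processing notes name RMA (robust multi-array average, version not given). The deposited values are an intensity per probe set on a linear scale, 1 column per sample, without pooling. RMA normally ends in log2 values, so a return to the linear scale by the authors is inferred from the values. A second deposited table holds the intensity of the same arrays after ComBat batch correction together with another series, per the file header. Its batches and covariates are not given in the sources used here. The table was used as an alternative and for its gene symbols, and its 7 columns of other samples were not used. In it, 2 values below a floor of 1 were set to the floor before log2 was taken.

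Both tables hold 45101 probe sets. Of these, 64 control probe sets, 5820 with no gene and 1399 with several genes were left out, and 37818 named a single gene. Each gene was represented by its probe set with the highest mean log2 value over the 9 arrays, which gave 20680 genes, 9528 of them with several probe sets. Symbols are those of the table. In the gene table of assembly GRCm38.p6, which served only for names and for which genes neighbour each other, 16151 symbols were found, 2090 more through a synonym, and 2439 had no match. The array and the build behind its annotation are not given in the sources used here, so no coordinates are printed.

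Intensities were turned to log2 with no filter and no further normalization. The genotypes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with genotype as the single term, and two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Fold changes are Ezh2-null minus WT on the log2 scale. Where a gene list fixed in advance is reported, p-values were also adjusted over the list alone. In total 28 lists with at least 5 measured members, 680 measured genes in all, were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Exact permutation tests ran over all splits of the arrays into 4 and 5.

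The named genes were Ezh2, Ezh1, Eed, Suz12, Cdkn2a, Egr1, Hoxa9 and Meis1 whatever their result, then the 12 furthest higher and the 12 furthest lower among genes that passed with no overlap between the genotypes, and up to 4 members of each list, those that passed or otherwise the 2 with the smallest p. Genes known only by a clone or locus number, 16 of the 103 that passed, were skipped. Had fewer than 12 passed in a direction, those that passed would have been filled up to 8 by the smallest p, which was not needed. Some of the genes that the rule gives are not reported here. Other genes named here were chosen after their values were seen. Among list members these are the further examples that passed only when adjusted over the list alone, the granule genes Ltf, Lcn2 and Camp, and Cdkn1b.

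The comparison, the lists, the rule for named genes and the alternative analyses were fixed before the data were examined. These were the batch-adjusted table, leaving out genes below the 40th percentile of mean log2 value, every probe set on its own, the mean of all probe sets of a gene, quantile normalization, centring on array medians, array weights, an intensity trend with robust variance, the replicate number as a block, leaving out each array in turn, and a threshold of 0.1. Added after seeing the data were the analysis without WT replicates 3 and 4 together, for lists also with an estimated correlation, the same arrays averaged into 1 sample, and the PRC2 list without Ezh2.

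The procedure was tested on simulated data for 20680 genes and the 9 arrays of the comparison of Ezh2-null with WT. Of 100 genes changed 2-fold 70% were called, of 100 changed 4-fold 97%, and 5.65% of the calls were unchanged genes. All 3 shifted lists and 0 others were called. The simulated genes varied independently of each other, whereas the estimated correlation in the data reached 0.69 for neutrophil maturation genes. The simulation therefore cannot show how often lists of correlated genes are called wrongly. The simulated arrays were also independent, with the same spread per gene in both genotypes. In the data WT replicates 3 and 4 were more alike than other WT pairs, and the WT group varied more. The simulated shares of single genes called, rightly or wrongly, therefore need not hold for these arrays.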

Results

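The series measured gene expression in a mouse model of acute myeloid leukaemia driven by MLL-AF9, the fusion of the histone methyltransferase MLL with AF9. Marrow of leukaemic secondary recipients was sorted for cells that carried both GFP, the mark of the retrovirus bearing the fusion gene, and YFP, the mark of Cre activity. RNA was amplified and hybridised to microarrays, 1 per sample, from 4 wild-type (WT) and 5 Ezh2-null leukaemias described in the labels as biological replicates. The number of arrays limits the precision of every value given here. The design sets the 2 genotypes against each other and so asks which transcripts differ in established leukaemia when Ezh2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), has been deleted.

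Ezh2 itself was lower on every Ezh2-null array than on any WT array. Its single probe set read 10.50 ± 0.49 on the log2 scale in WT (SD, n = 4) and 9.21 ± 0.18 in Ezh2-null leukaemias (SD, n = 5), which left 40.7% of the WT intensity. WT intensities ran from 887 to 1900 and Ezh2-null intensities from 495 to 658. The fold change of -1.30 (SE 0.21), or 2.46-fold lower, had an adjusted p of 0.0373 in limma, and a two-sided exact permutation test over every split of the arrays gave p = 0.00794, the smallest that 4 against 5 arrays allow. The position of this probe set relative to the deleted part of the gene was not used here, so its remaining signal does not measure how completely Ezh2 was deleted. In 11 of 20 alternative analyses the adjusted p stayed under the threshold of 0.05, with a range of 0.00632 to 0.149. It rose to 0.0974 without WT replicate 3, 0.103 without WT replicate 4, and 0.0787, 0.0924, 0.0748 and 0.0936 without Ezh2-null replicates 1, 2, 3 and 4, while the log2 change stayed between -1.53 and -0.99.

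The other core PRC2 genes did not pass the test. Ezh1, the paralogue of Ezh2, had a log2 change of -0.23 (adjusted p = 0.295), and the scaffold genes Eed and Suz12 had changes of -0.10 (adjusted p = 0.783) and -0.14 (adjusted p = 0.770). Cdkn2a, the cell cycle inhibitor locus silenced by Polycomb proteins in many cells, had log2 levels of 7.24 ± 0.23 in WT (SD, n = 4) and 7.14 ± 0.40 in Ezh2-null (SD, n = 5) and an adjusted p of 0.851 in limma. The MLL-fusion targets Hoxa9 and Meis1 remained bright, with log2 changes of -0.42 (adjusted p = 0.379) and 0.26 (adjusted p = 0.355). Egr1, an immediate early gene of monocytic differentiation, had a change of 1.06 and an adjusted p of 0.116.

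Outside PRC2, the genes furthest higher in Ezh2-null leukaemia were Bmpr1a, a type I receptor for bone morphogenetic proteins, at 25.6-fold on its brightest probe set, and Olfm4, a neutrophil granule glycoprotein, at 12.4-fold. Furthest lower were Tpm2, the beta chain of tropomyosin, at 16.2-fold, and Serpinf1, which encodes the secreted factor PEDF, at 10.6-fold. Bmi1, the Polycomb repressive complex 1 (PRC1) subunit with a role in stem cell self-renewal, rose 3.23-fold, while the CDK inhibitor gene Cdkn1a, which encodes p21, fell 2.35-fold. Of 20680 genes tested with limma, 103 passed at a Benjamini-Hochberg adjusted p under 0.05, 60 of them higher and 43 lower in Ezh2-null arrays. At least a 2-fold change was found for 42 of the higher and 34 of the lower genes. In all 103 the 2 genotypes did not overlap on any array, a state reached by 5.90% of all genes and by 1.59% under chance. The 103 were chosen by p on these same arrays, so their lack of overlap gives no further support. The chance share takes the arrays as independent. At an unadjusted p under 0.05 there were 3551 genes, against 1034 under chance.

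**Figure D1:**
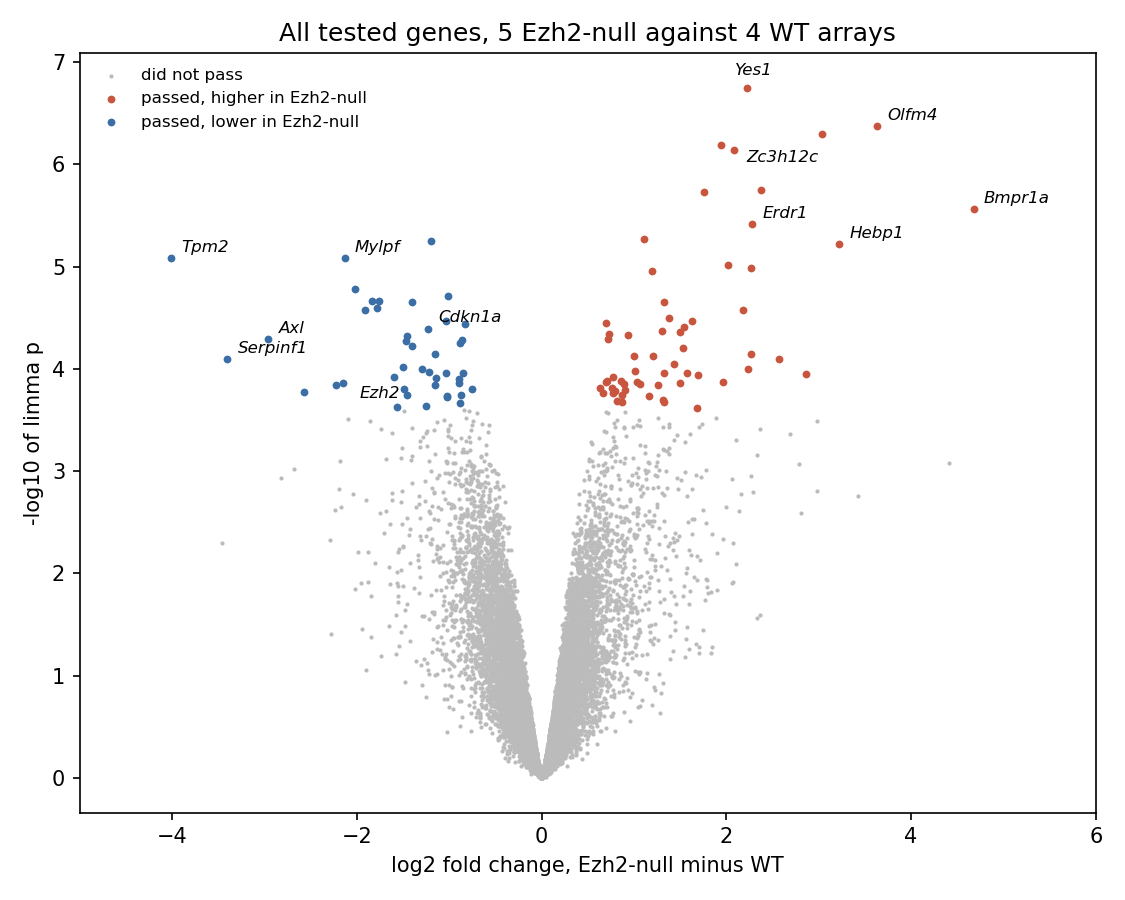
Each point is 1 of 20680 genes, with its log2 fold change (Ezh2-null minus WT) on the horizontal axis and -log10 of the limma p on the vertical axis. The 60 higher and 43 lower genes that passed are coloured, and Bmpr1a at 4.68 and Tpm2 at -4.02 lie at the edges.

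Bmpr1a was at 6.11 ± 0.33 in WT (log2, SD, n = 4) and at 10.79 ± 1.16 in Ezh2-null arrays (SD, n = 5), a change of 4.68 (SE 0.51, adjusted p = 0.00713). Of its 6 probe sets, 3 passed when each was tested on its own and none had the opposite sign, with changes from 0.52 to 4.68. The change of Bmpr1a was 2.76 as the mean of its probe sets and 3.53 in the batch-adjusted table. Olfm4 changed by 3.63 (SE 0.32, adjusted p = 0.00299), and Hebp1, a haem-binding protein gene, by 3.22 (SE 0.38, adjusted p = 0.0104). Others among the 12 furthest higher genes were the basement membrane collagen gene Col4a1 (2.58), the X-linked zinc finger gene Zxdb (2.38), Erdr1 (2.28), Sec16b of the endoplasmic reticulum (2.23), the Src family kinase gene Yes1 (2.23), the surface antigen gene Ly6k (2.18) and the CCCH zinc finger gene Zc3h12c (2.08). Their adjusted p ranged from 0.00299 to 0.0373.

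Tpm2 fell by 4.02 on the log2 scale (SE 0.49, adjusted p = 0.0123), from 10.79 ± 1.13 in WT (SD, n = 4) to 6.77 ± 0.61 (SD, n = 5). Of its 4 probe sets, 3 passed when each was tested on its own and 1 stood at -0.39. Serpinf1 fell by 3.40 (SE 0.54, adjusted p = 0.0328) with both of its probe sets. Axl, a receptor tyrosine kinase of the TAM family, fell by 2.96 (SE 0.45, adjusted p = 0.0261), although its other probe set stood at 0.03. The myogenic transcription factor gene Myog fell by 2.57, and the fast-muscle myosin light chain gene Mylpf fell by 2.13. Hfe, a regulator of cellular iron uptake, fell by 2.22, and Cad, which starts pyrimidine synthesis, fell by 1.91. The other probe set of Hfe stood at -0.38. Hfe passed in 9 of the 19 alternative analyses that held it, with a limma adjusted p of up to 0.159. Among those where it was lost were the mean of all probe sets of a gene and several fits with 1 array left out. The remaining genes among the 12 furthest lower were the ciliary transport gene Ttc21b (-2.15, other probe set -0.23), Wdr66 (-2.02), the carboxypeptidase gene Scpep1 (-1.83), Net1 (-1.78) and the vesicle trafficking gene Lrba (-1.76). Wdr66 and Lrba each had 2 further probe sets of opposite sign, none of which passed.

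**Figure D2:**
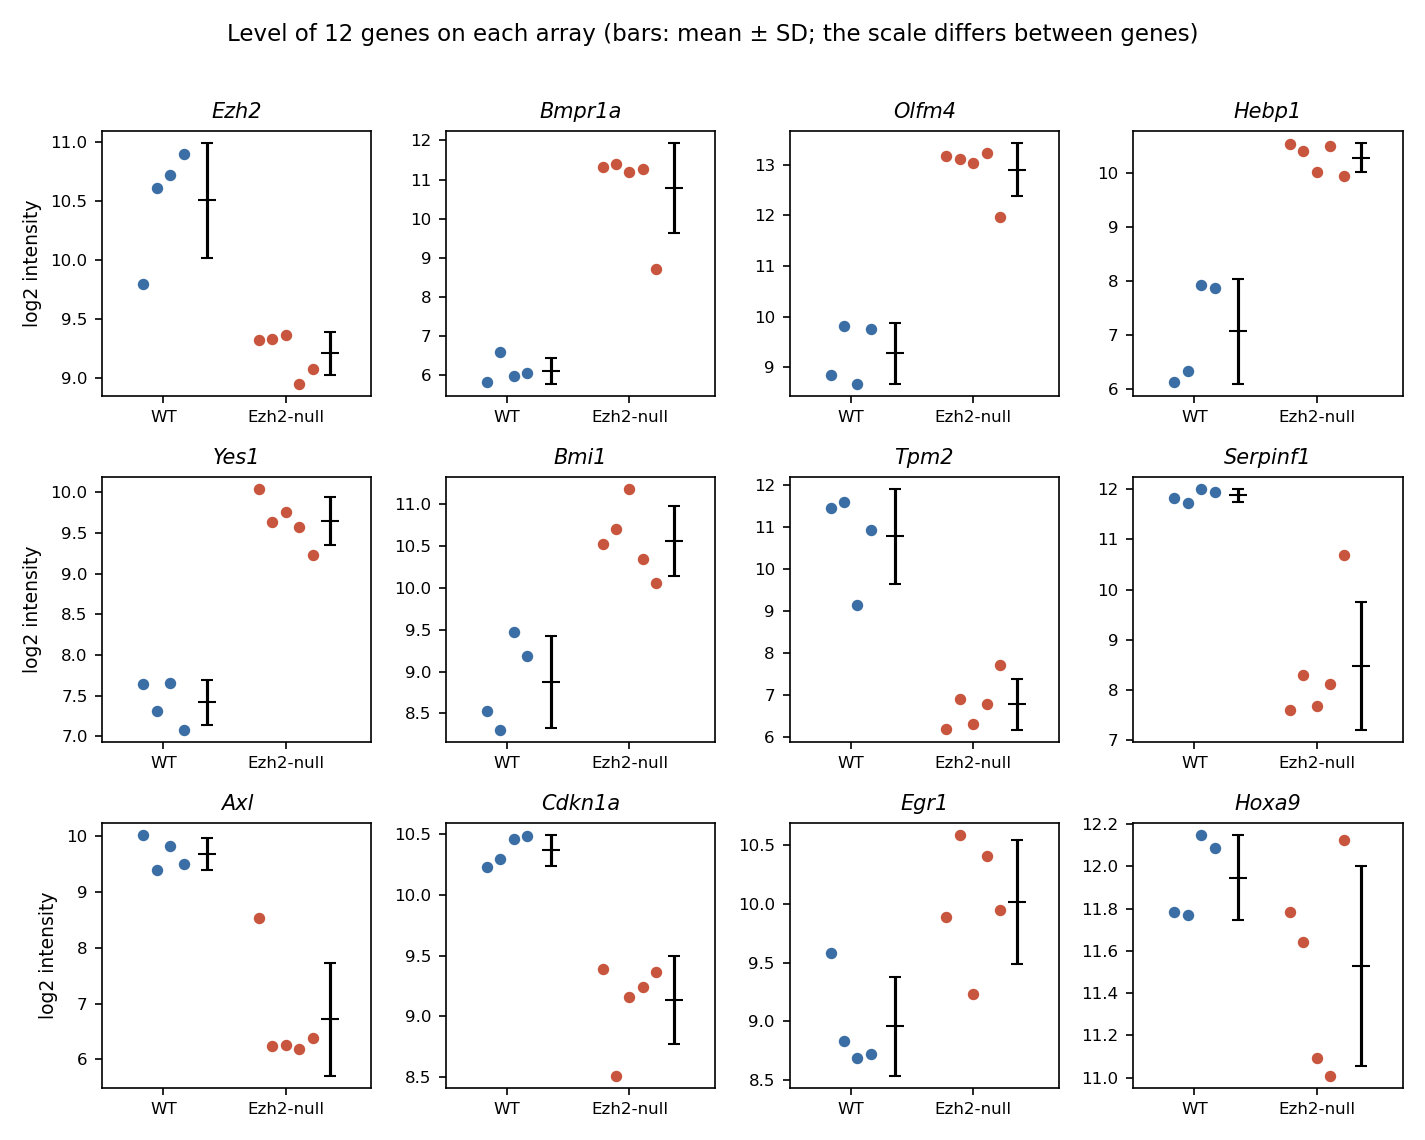
Log2 intensity of 12 genes on each of the 4 WT (blue) and 5 Ezh2-null (red) arrays, in order of replicate number, with the mean and SD of each genotype beside the points. Ezh2 ran from 8.95 to 9.36 on Ezh2-null arrays and from 9.79 to 10.89 on WT arrays, and Egr1 and Hoxa9 did not pass the test.

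The number of genes that passed moved strongly with single arrays. It was 241 without WT replicate 1, 330 without WT replicate 2, 24 without WT replicate 3, 17 without WT replicate 4, 24, 22, 29 and 31 without Ezh2-null replicates 1, 2, 3 and 4, and 221 without Ezh2-null replicate 5, and 13 of the 103 genes passed in all 9 of these fits. Higher genes did not outnumber lower ones without WT replicate 1 (97 and 144), without WT replicate 2 (132 and 198), with array weights (397 and 610), in the batch-adjusted table (94 and 108) or at an adjusted p under 0.1 (238 and 250). Among the 31 genes chosen by rule that passed, Olfm4, Hebp1, Zxdb, Erdr1, Yes1, Zc3h12c and Mylpf passed in all 20 alternative analyses, and Bmpr1a and Tpm2 in 19. Bmi1 passed in 14 and Cdkn1a in 13, and each was lost in several fits with 1 array left out.

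The arrays differed within the WT group more than within the Ezh2-null group. WT replicates 3 and 4 lay at 58.9 and 51.8 on the first principal component, which held 36.7% of the variance, against -0.67 and -2.33 for WT replicates 1 and 2 and -29.5 to -9.83 for the Ezh2-null arrays. Pearson correlations across genes, which are not independent replicates, ran from 0.956 to 0.988 in WT pairs, with WT replicates 3 and 4 the most alike, from 0.977 to 0.984 in Ezh2-null pairs and from 0.953 to 0.978 across genotypes. A median of 196 genes differed at least 4-fold in WT pairs, 67 in Ezh2-null pairs and 214.5 across genotypes. RNA quality, read as the log2 ratio of the 3' to the 5' control probe sets of Gapdh, was 1.62 ± 0.15 in WT (SD, n = 4) and 1.60 ± 0.04 in Ezh2-null arrays (SD, n = 5; exact permutation p = 0.754, two-sided). The same ratio of Actb gave an exact permutation p of 0.897. Within WT the Gapdh ratio was 1.80 and 1.69 on replicates 1 and 2 and 1.47 and 1.55 on replicates 3 and 4. Ezh2-null arrays lay between, at 1.56 to 1.65. The Actb ratio did not split WT in this way (-0.10 and 0.02 against -0.07 and -0.08). Whether RNA quality plays a part in the split within WT was not tested.

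Of 28 fixed gene lists tested with camera at a preset inter-gene correlation, 5 were higher and 5 lower in Ezh2-null leukaemia at an adjusted p under 0.05. With an estimated correlation camera passed none, the smallest adjusted p being 0.514 and 1 list lying under 0.05 before adjustment, so these calls rest on the preset value. The directional test of fry, which asks only whether the genes of a list move one way on balance, passed no list (smallest adjusted p = 0.0808, 9 lists under 0.05 before adjustment), and its mixed test, open to changes in either direction, passed 21. In the list results that follow, the score of an array is the mean over members of the log2 deviation from the mean of all arrays. Exact permutation p of these scores, not adjusted over lists, was 0.00794 for G2/M and for Myc and ribosome biogenesis genes, 0.0159 for mast cell, basophil and eosinophil genes, 0.0238 for electron transport genes and 0.0397 for PRC2 subunits. It was 0.0556 for neutrophil maturation and for immediate early and heat shock genes, 0.111 for stem and progenitor cell genes, 0.143 for megakaryocyte and platelet genes and 0.183 for G1/S genes (exact permutation, two-sided). Of the lists that did not pass at the preset correlation, cyclin-dependent kinase inhibitors had an exact permutation p of 0.00794 and PRC1 subunits 0.0159.

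Neutrophil maturation genes were higher together in Ezh2-null leukaemia. Of 23 measured members 22 had a positive log2 change, with a median of 1.21 (camera adjusted p = 9.90e-10, adjusted p = 0.514 with an estimated correlation). Olfm4 alone rose over all genes tested, and 4 rose when adjusted over the list alone, among them Csf3r, the G-CSF receptor gene, at 0.77 and the acute phase gene Hp at 0.58. The granule genes Ltf (1.60), Lcn2 (1.77) and Camp (0.77) did not pass. The list score was -1.82 and -1.27 on WT replicates 3 and 4, 0.10 and 0.24 on WT replicates 1 and 2, and between -0.30 and 0.97 on Ezh2-null arrays. Without WT replicates 3 and 4, an analysis chosen after seeing the data, the median was 0.23 and the camera adjusted p 0.0110, in a range of 1.57e-15 to 0.514 over all alternatives, and the adjusted p was 0.796 with an estimated correlation on those arrays. Without WT replicate 3 alone the median was 0.80.

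Mitotic genes and genes of ribosome production were lower. All 29 measured G2/M genes had a negative change, with a median of -0.51 (camera adjusted p = 6.54e-12, adjusted p = 0.514 with an estimated correlation). The spindle checkpoint kinase gene Bub1 fell by 1.15 over all genes tested, although its other, dimmer probe set stood at 0.46, and 14 members fell when adjusted over the list alone, among them the cyclin genes Ccnb2 (-0.84) and Ccnb1 (-0.77) and the kinetochore gene Cenpf (-0.73). The G2/M score was 0.28 ± 0.16 in WT (SD, n = 4) and -0.22 ± 0.17 in Ezh2-null arrays (SD, n = 5), with no overlap, and 0.41 and 0.42 on WT replicates 3 and 4. Myc and ribosome biogenesis genes had a median of -0.53 over 29 members (camera adjusted p = 3.10e-11, adjusted p = 0.514 with an estimated correlation). Cad fell over all genes tested and 11 members fell when adjusted over the list alone, among them the nucleolar genes Nop2 (-0.65) and Wdr43 (-0.66). Its score was 0.61 and 0.53 on WT replicates 3 and 4 and -0.07 and 0.09 on WT replicates 1 and 2. Without WT replicates 3 and 4 the medians were -0.32 for G2/M genes and -0.19 for Myc and ribosome biogenesis genes, and both lists still passed with the preset correlation, with adjusted p = 0.782 for each with an estimated correlation.

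G1/S genes and mitochondrial electron transport genes were lower on average by smaller amounts, a difference that rested mostly on WT replicates 3 and 4. For 30 G1/S genes the median was -0.29 (camera adjusted p = 1.05e-05, adjusted p = 0.687 with an estimated correlation), and none passed singly in limma, over all genes or adjusted over the list alone, with 10 at an unadjusted p under 0.05. Rrm1, a subunit of ribonucleotide reductase, stood at -0.57 and the DNA methylation cofactor Uhrf1 at -0.65. For 37 electron transport genes the median was -0.21 (camera adjusted p = 1.78e-07, adjusted p = 0.514 with an estimated correlation), again with no single call in limma, over all genes or adjusted over the list alone, with 11 members at an unadjusted p under 0.05, and with Atp5b at -0.43 and Uqcrfs1 at -0.49. On WT replicates 1 and 2 the score was -0.29 and -0.07 for G1/S genes and -0.05 and -0.03 for electron transport genes. Ezh2-null arrays ran from -0.25 to 0.13 for G1/S genes and from -0.18 to -0.01 for electron transport genes. Both scores were highest on WT replicates 3 and 4, at 0.57 and 0.49 for G1/S genes and 0.37 and 0.27 for electron transport genes. Without those arrays neither list passed, with medians of -0.04 and -0.09, and the G1/S median was -0.17 without WT replicate 3 alone and -0.48 without WT replicate 1.

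Stem and progenitor cell genes were higher, with a median of 0.30 over 24 members (camera adjusted p = 0.000484, adjusted p = 0.569 with an estimated correlation). Gata2, a transcription factor of stem cells and mast cells, stood at 1.46 and alone rose when adjusted over the list alone, none over all genes tested. Lmo2 stood at 0.40. The score was -0.78 and -0.67 on WT replicates 3 and 4 and between 0.03 and 0.45 on all other arrays. Megakaryocyte and platelet genes had a median of 0.18 over 18 members (camera adjusted p = 0.0328, adjusted p = 0.600 with an estimated correlation). None of them passed over all genes, the platelet glycoprotein gene Gp9 (0.54) alone rose when adjusted over the list alone, and Gp1ba stood at 0.78. Its score was -0.31 and -0.32 on WT replicates 3 and 4. Neither list passed without WT replicates 3 and 4, with medians of 0.14 and 0.08, and the megakaryocyte and platelet list was also lost without WT replicate 3 or WT replicate 4 alone.

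**Figure D3:**
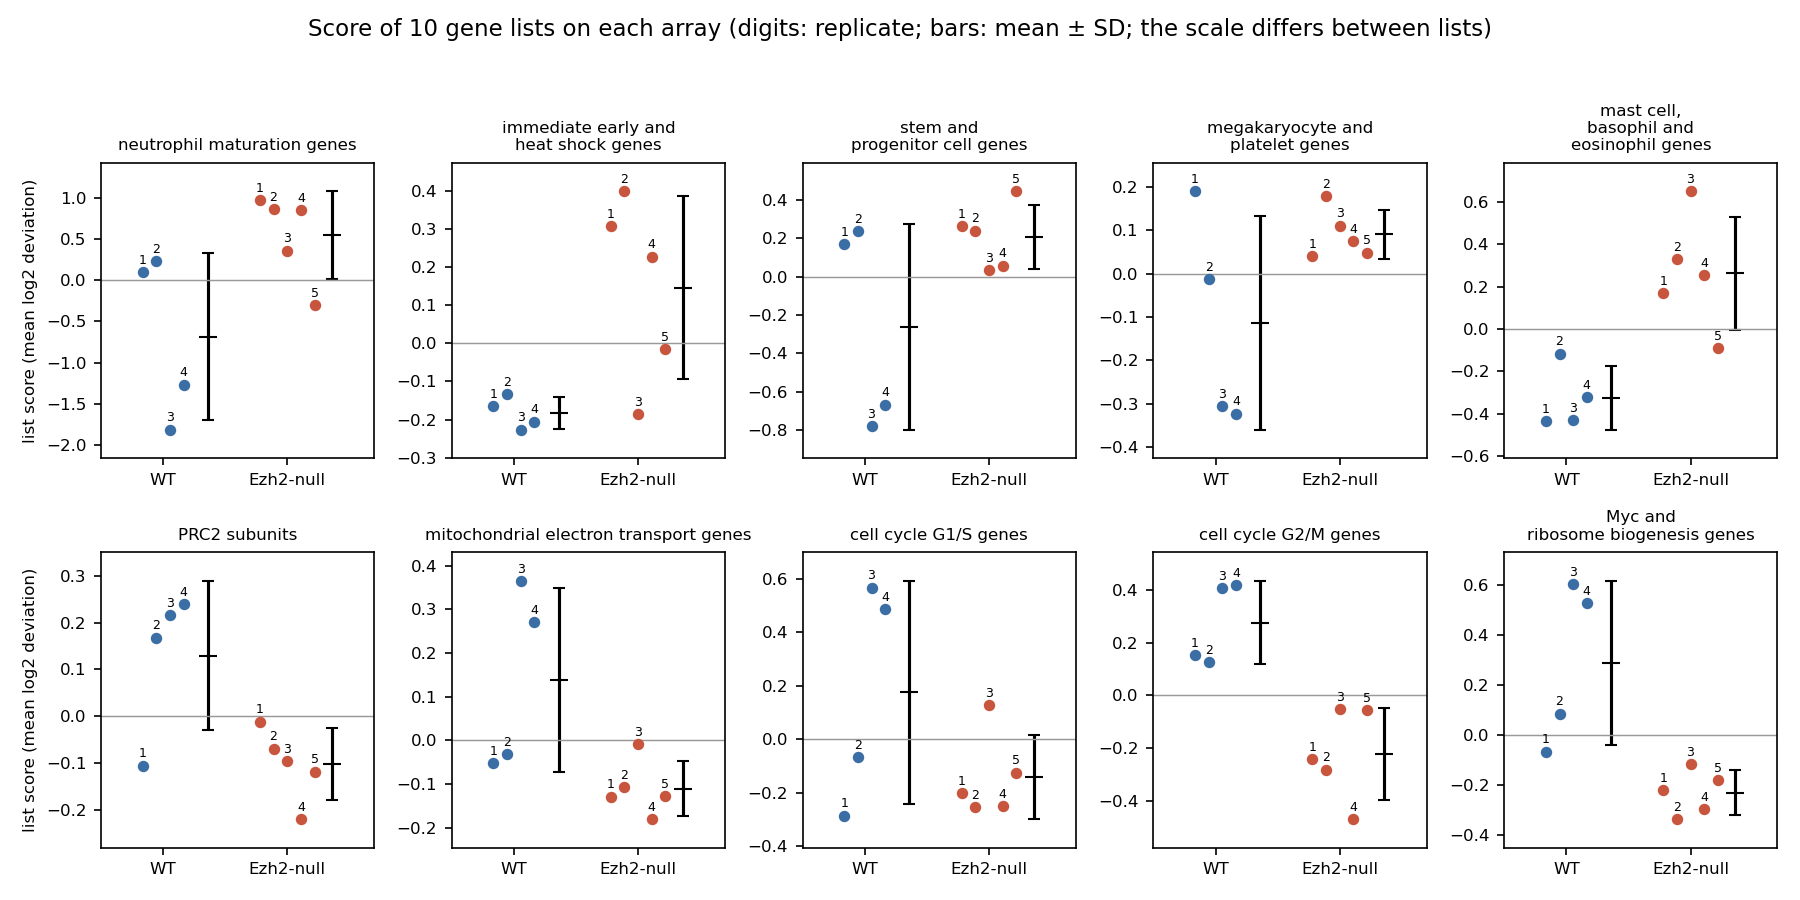
Scores of the 10 lists that passed camera with the preset correlation, as the mean log2 deviation of the members on each array, for 4 WT (blue) and 5 Ezh2-null (red) arrays, with replicate numbers at the points and the mean and SD of each genotype beside them. WT replicates 3 and 4 lie apart from WT replicates 1 and 2 in several lists, as for neutrophil maturation genes at -1.82 and -1.27.

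Mast cell, basophil and eosinophil genes had a median of 0.14 and a mean of 0.59 over 21 members (camera adjusted p = 0.0114, adjusted p = 0.514 with an estimated correlation). None passed over all genes, and 5 rose when adjusted over the list alone: the mast cell carboxypeptidase gene Cpa3 (1.38), Gata2, the eosinophil granule genes Prg2 and Prg3, and Siglec5. The score was -0.43 and -0.32 on WT replicates 3 and 4, between -0.44 and -0.12 over all WT arrays and between -0.09 and 0.65 in Ezh2-null arrays. This list did not pass without WT replicate 1 or after quantile normalization, where the median was 0.07. Its median was 0.09 without WT replicate 3 and 0.03 without WT replicates 3 and 4, and ran up to 0.81 without dim genes. Immediate early and heat shock genes had a median of 0.35 over 23 members (camera adjusted p = 0.00212, adjusted p = 0.514 with an estimated correlation). Over all alternatives the median of this list ran from 0.14 to 0.47. No member passed over all genes tested, while 10 rose and 2 fell when adjusted over the list alone, with Btg2 at 1.02 and Fosb at 1.04. Ezh2-null replicate 3, at -0.19, scored within the WT range of -0.23 to -0.13, and WT replicates 3 and 4 scored -0.23 and -0.21.

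PRC2 subunits had a median of -0.13 over 11 members (camera adjusted p = 0.0333, adjusted p = 0.514 with an estimated correlation), and Ezh2 was the single member that fell, both over all genes and when adjusted over the list alone. The score was 0.22 and 0.24 on WT replicates 3 and 4 and -0.11 on WT replicate 1. Without Ezh2 in the list the camera adjusted p was 0.165, in a range of 0.00384 to 0.526 over all alternatives, and the list was also lost without WT replicate 2, 3 or 4 or Ezh2-null replicate 4 or 5. Its median was -0.05 without WT replicate 3 and -0.06 without WT replicate 4. PRC1 subunits did not pass as a list (median 0.06, adjusted p = 0.557). Bmi1 rose by 1.69 with both probe sets passing, and Phc3, at 0.53, rose with it when adjusted over the list alone. Cyclin-dependent kinase inhibitors had a median of -0.10 over 6 members (adjusted p = 0.127), with Cdkn1a lower by either adjustment at a change of -1.23 (SE 0.18, adjusted p = 0.0254). With the mean of all probe sets of a gene the median of this list was -0.50 and it passed (camera adjusted p = 0.0108, range over all alternatives up to 0.514). Its member Cdkn1b stood at -0.10 on its brightest probe set and at -1.81 on the other. Cdkn1b lies beside 1190002F15Rik, which belongs to a cluster of changed genes on the chromosome of Ezh2 taken up under other observations. Whether that place plays a part in this list was not tested. The p53 target list, which shares Cdkn1a and had a median of -0.14, did not pass either (adjusted p = 0.684). Of its members, Cdkn1a alone fell over all genes, while 2 rose and 2, Cdkn1a among them, fell when adjusted over the list alone.

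Lists tied to the fusion gene and to PRC2 targets did not pass. MLL-fusion targets had a median of -0.02 over 24 members (adjusted p = 0.800), with none called over all genes, and with Lmo2 higher and Zeb2 (-0.55) and Cdk6 (-0.47) lower when adjusted over the list alone. MLL-fusion cofactors and other chromatin regulators had a median of -0.04 (adjusted p = 0.815), none called over all genes, and 3 higher and 2 lower when adjusted over the list alone, with Dnmt3b at -0.96 and Aff1 at 0.34. No member of 3 further lists passed in limma, either over all genes or adjusted over the list alone, with 4, 1 and 3 members at an unadjusted p under 0.05. These were classic developmental PRC2 targets (50 members, median 0.07, adjusted p = 0.268, Lhx2 at -0.68 and Wnt5a at 0.58), Hoxb, Hoxc and Hoxd genes (25 members, median 0.10, adjusted p = 0.231, Hoxb3 at 0.30 and Hoxc8 at 0.26) and imprinted genes (27 members, median 0.05, adjusted p = 0.815, Igf2r at -1.56 and Nnat at 0.82).

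Monocyte and macrophage genes had a median of -0.02 over 33 members (adjusted p = 0.742), and the chemokine receptor gene Ccr2 (-1.52) alone fell when adjusted over the list alone, none over all genes. Antigen presentation and dendritic cell genes (median -0.17, adjusted p = 0.557), B lymphoid genes (median 0.08, adjusted p = 0.556), T and NK cell genes (median 0.05, adjusted p = 0.395) and stromal and endothelial genes (median 0.03, adjusted p = 0.635) held no single call in limma by either adjustment, with 3, 2, 4 and 1 members at an unadjusted p under 0.05. Their best-ranked members were Cd209a (1.34) and Bst2 (-0.41), Blnk (-0.47) and Rag2 (0.39), Klrb1c (0.53) and Cd5 (0.71), and Col1a1 (0.52) and Fabp4 (-0.67). In the erythroid list (22 members, median 0.01, adjusted p = 0.556) the transferrin receptor gene Tfrc fell by 1.25 (adjusted p = 0.0471) and the haem synthesis gene Cpox fell by 1.03 (adjusted p = 0.0373), and 3 members fell when adjusted over the list alone. Tfrc passed in 7 of 20 alternative analyses and in none with 1 array left out, with an adjusted p of up to 0.112, and Cpox passed in 10 of 20. Primary granule genes had a median of -0.20 over 11 members (adjusted p = 0.141), with none called over all genes and with Nkg7 (1.25) higher and 2 members including Igfbp4 (-2.18) lower when adjusted over the list alone. That list passed as lower with array weights (median -0.48, adjusted p = 0.0208), without WT replicate 1 (adjusted p = 0.00858) and without Ezh2-null replicate 5 (adjusted p = 0.0496), in a range up to 0.778. Its median turned to 0.12 without WT replicates 3 and 4, where it did not pass. Antigen presentation genes were lower without WT replicates 3 and 4 at the preset correlation alone.

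Among the last lists, interferon response genes did not pass (40 members, median 0.02, adjusted p = 0.596). Ifi27l2a, an interferon-induced gene, fell by 1.22 (adjusted p = 0.0373), and 4 members were higher and 3 lower when adjusted over the list alone. Apoptosis regulators (22 members, median 0.04, adjusted p = 0.794) had no call in limma by either adjustment and 5 at an unadjusted p under 0.05, with the BH3-only gene Bmf at 0.61 and Casp8 at -0.38. Glycolysis and hypoxia genes (26 members, median -0.13, adjusted p = 0.231) had none over all genes, and Ndrg1 (1.31) higher and 2 members including Pdk1 (-0.57) lower when adjusted over the list alone. For imprinted, B lymphoid, erythroid, interferon response and apoptosis genes the median, the mean and the direction of the camera test differed in sign.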

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

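The count over the probe sets of Bmpr1a was chosen only after the result was seen. Each gene named by rule, each list score and 4 measures of array quality were tested in each genotype for 1 array that lay apart from the others by Dixon's 95% limit, in 212 groups of values, of which 18 passed where chance alone gives about 1 in 20, or 10.6.

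Ezh2-null replicate 5 held 5 of the 18. Bmpr1a read 8.72 there (log2) and 11.21 to 11.40 on the other Ezh2-null arrays, Olfm4 11.97 against 13.04 to 13.24, Col4a1 7.43 against 9.27 to 9.65, Serpinf1 10.68 against at most 8.30, and Rag2 7.04 against 6.64 to 6.69. For the first 4 of these genes the value lay on the side of the WT arrays. All 6 probe sets of Bmpr1a were lowest on this array within the Ezh2-null group. Ezh2 itself read 9.07 there, within the span of 8.95 to 9.36 of its group.

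WT replicate 1 held 4. Egr1 read 9.59 against 8.69 to 8.83 on the other WT arrays, Col4a1 6.83 against 6.35 to 6.43, and Scpep1 10.25 against 9.62 to 9.67. The score of cyclin-dependent kinase inhibitors was 0.52 there against 0.08 to 0.11. WT replicate 3 held Cdkn2a, at 7.58 where the 3 others all read 7.13, and Cpa3, at 5.63 against 6.08 to 6.15.

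On Ezh2-null replicate 3, Ly6k read 10.36 against 8.81 to 9.16, Igf2r 6.90 against 8.23 to 8.64, Gp1ba 8.08 against 6.97 to 7.24, and the score of PRC1 subunits was 0.15 against 0.00 to 0.03. Zc3h12c on Ezh2-null replicate 2 read 9.04 against 8.52 to 8.63, and Cdkn1a 8.51 against 9.16 to 9.39. Axl on Ezh2-null replicate 1 read 8.53 against 6.19 to 6.38. No explanation for these single values was tested.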

How the results depend on the processing

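The analyses without WT replicates 3 and 4 or with them averaged, and the PRC2 list without Ezh2, were chosen only after the result was seen. Against 103 genes, the batch-adjusted table gave 202 (99 shared, 94 higher and 108 lower), array weights 1007, an adjusted p under 0.1 488, single probe sets 162, the analysis without WT replicates 3 and 4 61 (20 shared), and their average as 1 sample 22. Leaving out 1 array gave 17 (WT replicate 4) to 330 (WT replicate 2). The other settings gave 86 to 145, including 135 with replicate number as a block, of which 54 were shared. Replicate numbers did not pair across genotypes, with correlations of deviations from -0.14 to 0.13. Against 10 lists, 6 passed without WT replicates 3 and 4, 0 with an estimated correlation and 7 to 11 otherwise. G1/S genes then had a median of -0.0376 and the camera test turned upwards (adjusted p = 0.718, range from 3.82e-10), the only reversal of a called result. Lists that did not pass changed direction in 22 comparisons, 5 of them under quantile normalization, and in 10 with 1 array left out. Cdkn2a changed direction with the batch-adjusted table (0.05), without WT replicate 3 (0.02) and without Ezh2-null replicate 3 (0.01). Eed and Suz12, which did not pass, turned to 0.13 and 0.21 without WT replicates 3 and 4 and to 0.01 each without WT replicate 3. Named genes kept their result in 710 of 798 further comparisons (56 lost, 32 gained) and in 531 of 666 with 1 array left out (123 lost, 12 gained), and lists in 283 of 309 (22 lost, 3 gained) and 242 of 252 (8 lost, 2 gained).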

Other observations

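The genes in this part were chosen after their values were seen, and so were the tests on neighbouring genes, on cells like those of the WT arrays, on the place of the Ezh2 probe set and on WT replicates 3 and 4, left out or averaged. Further single genes passed in limma after Benjamini-Hochberg adjustment. Kdm5b, a demethylase of histone H3 lysine 4, rose by 1.26 on the log2 scale (adjusted p = 0.0373), and Ash2l, a core subunit of the methyltransferases for the same residue, fell by 0.86 (adjusted p = 0.0261). The centriole kinase gene Plk4 fell by 0.89. Among other genes that rose were the myosin light chain gene Myl10 (1.94), the keratin gene Krt18 (1.49), the ephrin receptor gene Epha7 (1.69), the zinc finger oncogene Plag1 (1.33) and the Wnt agonist gene Rspo1 (1.38). The leukocyte surface receptor genes Cd84 (1.33) and Cd300lb (1.53) rose, and Fads1 (-1.40), the kinase gene Matk (-1.45) and the coactivator gene Ppargc1b (-1.49) fell.

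The eosinophil granule genes Prg2 and Prg3 did not pass over all genes and passed when adjusted over their list alone. Prg2 stood at 3.42 (adjusted p = 0.0894) and Prg3 at 2.98 (adjusted p = 0.0862), with SDs of 1.86 and 1.62 in Ezh2-null arrays (n = 5). Cd34 stood at 1.90 (adjusted p = 0.137) and Erg at 1.79 (adjusted p = 0.180). Besides Hfe, Tfrc and Cpox, the iron-sulfur cluster gene Ciapin1 (-0.75, adjusted p = 0.0388) fell. The median over 5 further haem synthesis genes was -0.00933, with 3 of the 5 below 0, so a lower level of the haem synthesis pathway as a whole was neither shown nor excluded. Alad, a further gene of the pathway, was not analysed here.

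Antigen presentation genes separated the WT arrays rather than the genotypes. Their score was 0.81 and 0.71 on WT replicates 1 and 2, -0.69 and -0.61 on WT replicates 3 and 4, and between -0.40 and 0.50 on Ezh2-null arrays. Without WT replicates 3 and 4 the list was lower in Ezh2-null arrays at the preset correlation, with a median of -0.59 (camera adjusted p = 4.99e-06, range over all alternatives up to 0.893). With an estimated correlation on the same arrays it did not pass (camera adjusted p = 0.782).

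For the genes changed between the genotypes, chance in how the arrays were grouped was made less likely but was not excluded. Only 1 of 100 splits, the real one, gave as many as 103 genes (highest other 91, Ezh2-null replicates 1 to 4 against the rest). With WT replicates 3 and 4 averaged, only 1 of 56 gave as many as 22 (highest other 7). Both tests take the samples as leukaemias of separate origin, which the sources used here do not state. Passenger DNA at the targeted allele as the main cause was excluded, with 11.5% of changed genes on the chromosome of Ezh2, 5.45% of tested genes there, and 0 of the 200 genes nearest to Ezh2 changed. A stretch of DNA of another origin further along that chromosome may account for some. Hebp1, 8430419L09Rik, Ddx47 and 1190002F15Rik lay within 10 neighbouring genes (permutation p = 0.00160). Besides Ezh2, all 11 changed genes of the chromosome lay on the same side of Ezh2. Ezh2 was at place 233 of the 995 tested genes there, and the first changed gene of the cluster at place 896. Mgst1, Ldhb and Dennd5b, also changed, lay beyond the cluster. The chromosome's share gave p = 0.0199 in Fisher's exact test on it alone. That share did not pass over all 21 chromosomes (Benjamini-Hochberg adjusted p = 0.387). Genome-wide pairs of changed genes within 25 genes did not pass either (16 against a mean of 12.5, permutation p = 0.189). Both of these look across the whole genome, so they cannot decide about a single stretch. Neighbours can also share regulation, which was not told apart from DNA of another origin. Ddx47 stood at -1.20 on the probe set used and at -0.24 and 0.23 on its others. For 8430419L09Rik the change was 1.96 on the probe set used and 0.38 and 0.75 on its others. What these unlike probe sets mean for the cluster was not tested. Differences between single leukaemias of any genotype could not be told apart from genotype, since WT pairs had 0.914 times as many genes at least 4-fold apart as pairs across genotypes (medians 196 and 214.5), although Ezh2-null pairs had 67, WT replicates 1 and 2 had 105 and WT replicates 3 and 4 had 21.

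The Ezh2 signal left in Ezh2-null arrays was weighed against 2 explanations. Cells like those of the WT arrays among the sorted cells would bring all WT transcripts alike, but 3 genes, Axl, Serpinf1 and Tpm2, fell further than Ezh2 with 95% intervals that did not meet its own. This leaves open cells of the same leukaemia that kept Ezh2. That the probe set lies outside the deleted part of the gene could not be tested with 1 probe set of unknown position. No biological explanation was tested.

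The higher neutrophil maturation genes may owe much of their size to the 2 WT arrays that stand apart, since the median was 0.23 without them against 1.21, and whether they share a primary leukaemia is not given in the sources used here. The sort for GFP and YFP should leave out neutrophils of normal origin, so the cells in question would be mature neutrophils that descend from the leukaemia. Such mature neutrophils among the sorted cells were not excluded: 1 of 6 abundant transcripts, S100a9, had a 95% interval below the median of the list, ending at 1.19. By the rule written beforehand this would have excluded them, but the rule was changed after the value was seen, because S100a9 reached 14.92 where the brightest value was 15.08, and the Ezh2-null means of 3 of the 6 lay within 1 of it. A direct effect of Ezh2 loss on neutrophil maturation was not separated from these.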
